A study of Mus musculus with 4 samples.

How the data were processed

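The data were 4 SMART-seq libraries of CD8 T cells from mouse tumours, 1 per group: Pmel-I cells transduced with the MigRI vector or with Klf4, and PD1-positive cells from control (WT) mice and from mice labelled Klf4 cKO. Per the labels' protocols, RNA was taken up in TRI Reagent and libraries were made with the SMART-seq v4 ultra low input kit. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, StringTie and edgeR and the genome build was mm10. Their versions, their roles and the gene annotation are not given in the sources used here. Gene-level TPM values were deposited by the authors, 1 table per library. TPM divides by transcript length and scales each library to the same total, so a few abundant or short transcripts lower the value of every other gene. TPM keeps no depth, so no counting error can be given. The kit does not mark strand, so reads of overlapping genes could not be told apart, and values of granzyme, hemoglobin and tryptase paralogs could be split between copies.

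The tables held 45777 entries each. In the control table, 26 gene symbols had been turned into calendar dates. Of these, 22 were mapped back by name, and the 4 genes behind 2 ambiguous date names were left out of all libraries, which left 45773 genes. Genes with a mean of at least 1 TPM over the 4 libraries were called measured (12570 genes). A gene listed at 0 in 1 library and at 50 TPM or more in another occurred 6 times in MigRI, 21 times in Klf4-transduced, 9 times in control and 2 times in the library labelled Klf4 cKO. An exact 0 can be a failed estimate, so such genes are given as listed at 0, without a fold.

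Differences between groups are reported only within an experiment, as the difference of log2(TPM + 1), which understates the change of low genes. Between experiments, levels are set side by side without a difference. A pseudocount of 1 was used and a difference of at least 1 log2 (2-fold) was called. With 1 library per group there is no test and no p-value, and all counts describe these libraries. Because the median over measured genes moved in both comparisons, differences are also given relative to it. The median of each of 31 gene lists (416 members found, 369 measured) was set against 10000 random lists of the same size drawn from 20 bins of mean level with seed 20, and lists outside percentiles 2.5 to 97.5 were called. Lists with fewer than 3 measured genes were given as values.

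Named genes followed a rule. They were Klf4, the 10 largest and 10 smallest differences in each comparison among genes at 20 TPM or more in the higher library, up to 4 members of each list with the largest difference, the 2 highest members of each list for other cells, and the 10 genes each way with the largest smaller difference among opposite genes at 10 TPM or more. Predicted genes, small RNAs with the name prefixes Mir, Snor, Scarna, Rnu or n-R, receptor segments, mitochondrial genes and ribosomal protein genes were left out. This held for the largest and smallest differences and for the opposite genes. These prefixes do not cover Rn7sk and the tRNA genes n-TEttc4 and n-TFgaa5, which stayed among the largest and smallest differences. The text gives values for some of the genes the rule picked, and 2 list members are left out of the counts of named genes and are not reported here. Prf1, Havcr2, Cd3e, Spp1, Tcf7, Mki67, Top2a and the T cell receptor genes were chosen after their values were seen. The groups, the filter, the pseudocount, the lists, the naming rule and a set of processing alternatives were set before the data were examined.

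The alternatives set beforehand were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 or 10 TPM, median of ratios scaling, quantile normalization, TPM rescaled without mitochondrial, ribosomal protein and receptor segment genes, and TPM rescaled without the 50 most abundant genes. Alternatives chosen after seeing the data were random lists matched on level and transcript length, differences relative to the median gene, differences relative to Trac, Trbc1 and Trbc2, and coding genes of at least 1000 nucleotides. Transcript lengths and coordinates came from GENCODE vM21 on mm10, which gave a length for 11761 measured genes (93.6%). The length of a gene was that of its longest annotated transcript, which may not be the one expressed.

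The scripts were tested on simulated data. For Klf4 over MigRI, on 11465 genes, 94% of genes raised by 2 log2 and 88% of genes lowered by 2 log2 were called, with 80% and 68% at 1.5 log2, and 0.790% of unchanged genes were called. For the library labelled Klf4 cKO over control, on 11025 genes, the shares were 98%, 86%, 80% and 52%, with 0.730% of unchanged genes called. Of unchanged lists of randomly drawn genes, 5.5% and 5.0% fell outside the percentiles. The noise of the simulation was a setting and not an estimate from replicates. The simulated libraries were also scaled by median of ratios, which the deposited TPM were not. These shares are therefore not error rates for the counts reported below. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.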

Results

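Gene expression was measured by SMART-seq, a method that amplifies full-length cDNA from small amounts of RNA, in 4 libraries of mouse CD8 T cells isolated from tumours. In the gain experiment, Pmel-I CD8 T cells, which carry a transgenic receptor for the melanocyte antigen gp100, were transduced with the empty retroviral vector MigRI or with Klf4 and transferred on day 7 into Rag2-deficient mice bearing MC38 colon carcinoma that expresses gp100. GFP-positive infiltrating cells were isolated on day 15. In the loss experiment, CD8 T cells positive for the inhibitory receptor PD1 were isolated on day 14 from MC38 tumours of control (WT) mice and of mice labelled Klf4 cKO. Tumours were started from 300000 cells, and 10000 to 20000 T cells were collected per sample. Each of the 4 groups held 1 library, so no difference has a replicate check, no spread between animals can be given and no p-value was computed. Every direction below describes 1 library against another.

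TPM values keep no read depth, so the depth is unknown and no counting interval is given. Genes at 1 TPM or more numbered 11011 in the MigRI library, 13170 in the Klf4-transduced library, 10542 in the control (WT) library and 11937 in the library labelled Klf4 cKO. The 10 highest genes took 13.5%, 8.79%, 21.7% and 17.8% of all TPM in the same order. Genes whose longest transcript is shorter than 1000 nucleotides took 38.8%, 21.7%, 54.9% and 41.3%. The median difference over the 12570 measured genes was 0.79 log2 for Klf4-transduced over MigRI and 0.74 log2 for the library labelled Klf4 cKO over control. Relative log2 differences below are differences of log2(TPM + 1) minus these medians.

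Klf4, a zinc finger transcription factor encoded on mm10 chromosome 4 from 55527143 to 55532466 on the minus strand, was at 8.69 TPM in the MigRI library, 26.05 TPM in the Klf4-transduced library, 7.52 TPM in the control library and 9.28 TPM in the library labelled Klf4 cKO. The Klf4-transduced library was higher than MigRI by 1.48 log2 as deposited and by 0.69 log2 relative to the median gene. The relative value is below 2-fold and below the median of the Kruppel-like factor list, 1.17 log2. The rise of Klf4 was thus not set apart from that of its family and checks the transduction label only weakly. The library labelled Klf4 cKO was higher than control by 0.27 log2 as deposited, while its relative log2 difference was -0.47, so the direction turned with the scaling. The labels do not say which part of the gene was deleted, and a gene-level value may miss the loss of a part. Klf4 therefore does not check the cKO label, and every direction drawn from that library rests on the label alone.

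**Figure D1:**
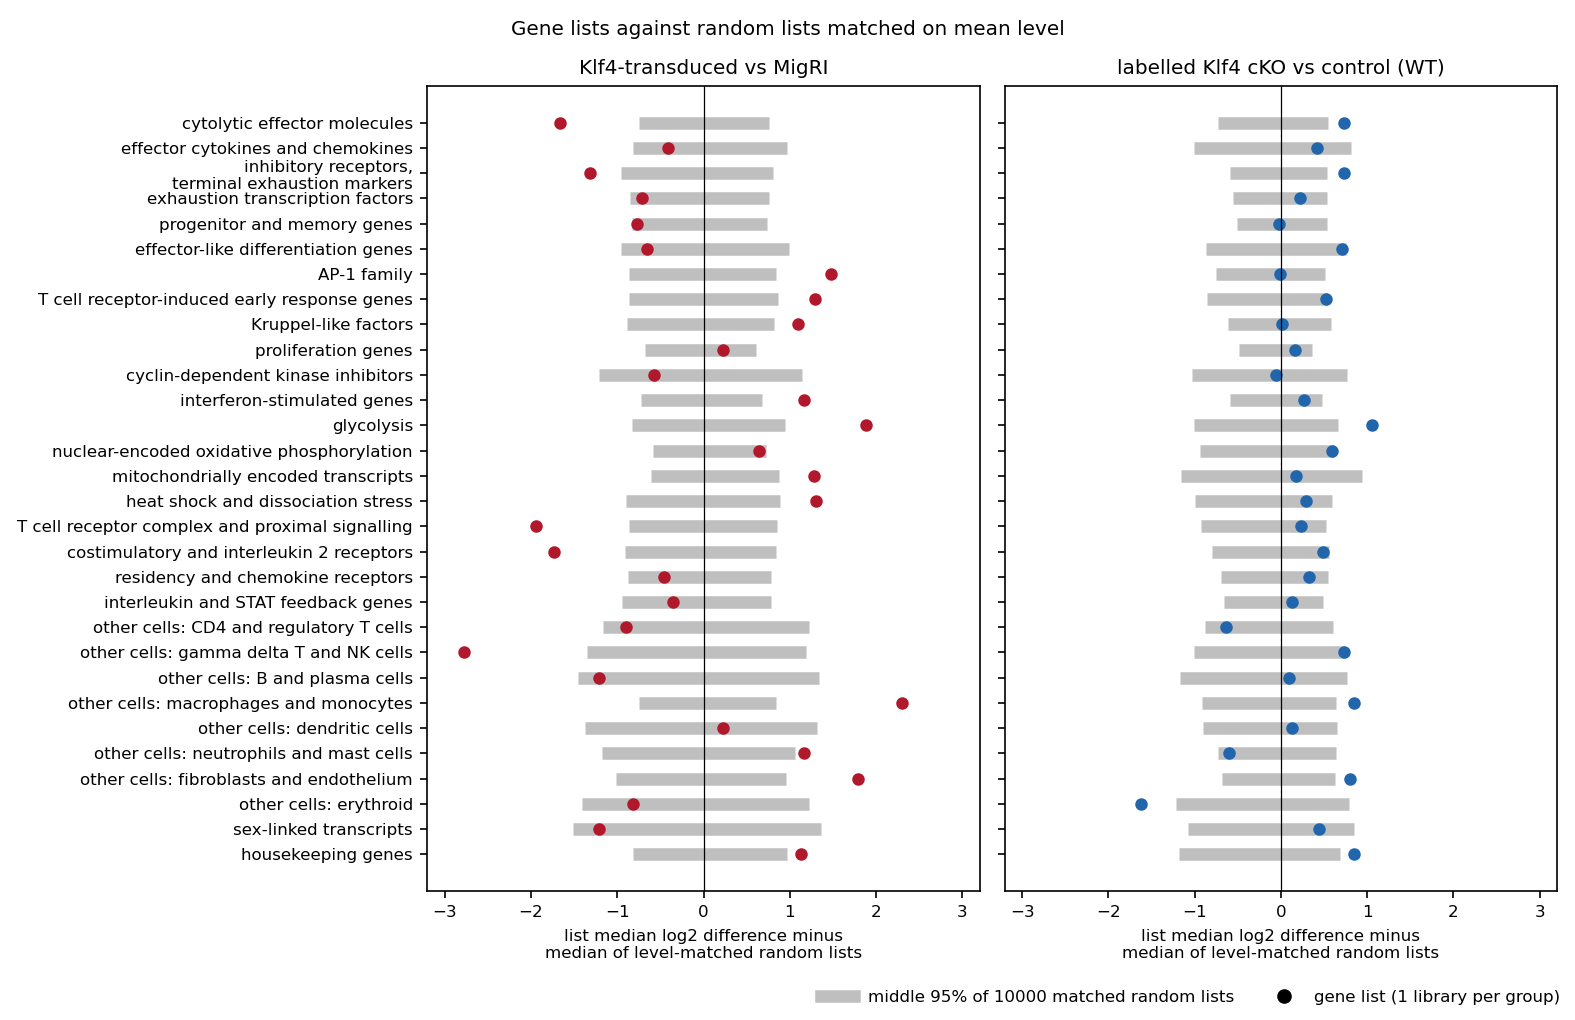
Median log2 difference of each gene list minus the median of level-matched random lists (x axis, log2 units) for Klf4-transduced over MigRI (left) and for the library labelled Klf4 cKO over control (right). Points are gene lists from 1 library per group, and grey bars span the middle 95% of 10000 random lists. The cytolytic list lies at -1.66 on the left and at 0.73 on the right, and the macrophage list at 2.30 and 0.85. Relative to the T cell receptor constant genes, both cytolytic medians and both inhibitory receptor medians changed sign.

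The comparison of Klf4-transduced with MigRI cells asked which transcripts differed in tumour-infiltrating CD8 T cells that had been transduced with Klf4 before transfer. Genes of the T cell receptor complex and several granzymes were lower in the Klf4-transduced library, while immediate early transcription factors, interferon-stimulated genes and glycolytic enzymes were higher. Cd3d and Cd3g, chains of the receptor complex, were at 1230 and 1776 TPM in MigRI and at 56.0 and 93.6 TPM with Klf4, relative log2 differences of -5.22 and -5.02. Jun, an AP-1 transcription factor, was at 84.5 TPM in MigRI and 1381 TPM with Klf4, a relative log2 difference of 3.22. Whether the higher immediate early, interferon-stimulated and glycolytic transcripts came from T cells or from RNA of other cells was not tested. Markers of macrophages and fibroblasts were higher in the same library: Cd74, the invariant chain of class II antigen presentation, was at 711 and 2251 TPM, and Sparc, a matrix protein of fibroblasts, at 89.3 and 821 TPM.

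Of 18 measured cytolytic genes, 14 were at least 2-fold lower and 1 at least 2-fold higher relative to the median gene, and the list median lay 1.66 log2 below that of level-matched lists (percentile 0). As deposited, the numbers were 12 lower and 2 higher. Gzmc was at 668 TPM in MigRI and 87.1 TPM with Klf4, and Gzme at 20.1 and 0.511 TPM, relative log2 differences of -3.72 and -4.60. Gzmf was at 53.4 TPM in MigRI and listed at 0 with Klf4. Nkg7, a granule protein, was at 10580 and 982 TPM, a relative log2 difference of -4.22. Gzmb, the main granzyme of effector cells, was at 1003 and 1007 TPM, a relative log2 difference of -0.79. Prf1, the pore-forming perforin, which was chosen after its values were seen, was at 31.1 and 69.7 TPM, a relative log2 difference of 0.34. The receptor itself was lower too: the constant genes Trac, Trbc1 and Trbc2 were 4.04-fold lower in median, and against them the cytolytic median was higher by 0.62 log2.

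The receptor complex list lay 1.95 log2 below its matched lists (percentile 0.01), with 12 of 14 genes at least 2-fold lower relative to the median gene and 0 higher. Costimulatory and interleukin 2 receptors lay 1.73 log2 below theirs (percentile 0), with 11 of 14 lower and 0 higher. Tnfrsf4, the OX40 receptor, was at 1581 and 204 TPM, and Cd226 at 19.1 and 1.34 TPM. Inhibitory receptors lay 1.31 log2 below theirs (percentile 0.32), with 7 of 13 lower and 1 higher. As deposited, 4 were at least 2-fold lower and 4 higher. Layn was at 1.19 and 11.2 TPM, a relative log2 difference of 1.69. Havcr2, chosen after its values were seen, was at 6.83 and 19.7 TPM, a relative log2 difference of 0.61. Tigit was at 23.1 and 2.65 TPM, Ctla4 at 63.5 and 12.5 TPM, and Pdcd1, which encodes PD1, at 123.5 and 36.2 TPM, relative log2 differences of -3.52, -3.05 and -2.54. The list of gamma delta T and NK cell markers lay 2.78 log2 below its matched lists (percentile 0.02), with 3 of 5 lower and 1 higher. Against the receptor constant genes these 4 medians turned sign, to 0.32 log2 for the receptor complex, 0.74 for costimulatory receptors, 1.55 for inhibitory receptors and 0.17 for gamma delta T and NK cell markers.

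Of 14 AP-1 family genes, 7 were at least 2-fold higher and 2 lower relative to the median gene, and the list lay 1.48 log2 above its matched lists (percentile 99.96). Fos was at 149 TPM in MigRI and 1594 TPM with Klf4, and Fosl1 at 10.9 and 177 TPM, relative log2 differences of 2.61 and 3.11. Batf went the other way, at 124 and 18.1 TPM. Early response genes lay 1.30 log2 above their matched lists (percentile 99.89), with 6 of 14 higher and 1 lower. Egr1 was at 18.5 and 373 TPM, and Zfp36, which destabilizes cytokine mRNA, at 65.1 and 1121 TPM. Among Kruppel-like factors, 7 of 12 were higher and 1 lower, and the list lay 1.10 log2 above its matched lists (percentile 99.63). Klf2, a quiescence factor, was at 20.2 and 274 TPM, and Klf9 at 3.30 and 41.0 TPM, relative log2 differences of 2.91 and 2.49.

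Interferon-stimulated genes lay 1.16 log2 above their matched lists (percentile 99.96), with 11 of 23 at least 2-fold higher relative to the median gene and 1 lower. Rsad2 was at 9.04 and 125 TPM, and Oasl1 at 7.55 and 108 TPM, relative log2 differences of 2.86 and 2.88. Glycolytic genes lay 1.88 log2 above theirs (percentile 100), with 9 of 15 higher and 1 lower. Slc2a1, the glucose transporter GLUT1, was at 13.5 and 187 TPM, and Pkm at 377 and 2753 TPM. Heat shock and dissociation stress genes lay 1.30 log2 above theirs (percentile 99.68), with Dnajb1 at 45.1 and 200.3 TPM. Mitochondrially encoded transcripts lay 1.28 log2 above theirs (percentile 99.74), although 0 of 15 were at least 2-fold higher relative to the median gene and 3 were lower. Housekeeping genes lay 1.13 log2 above theirs (percentile 99.02), with 1 of 12 higher and 1 lower.

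The macrophage and monocyte list lay 2.30 log2 above its matched lists (percentile 100), with 12 of 15 genes at least 2-fold higher relative to the median gene and 0 lower. The fibroblast and endothelium list lay 1.79 log2 above its own (percentile 100), with 8 of 9 higher and 1 lower. Dcn, a matrix proteoglycan, was at 31.1 TPM in MigRI and 302 TPM with Klf4. The neutrophil and mast cell list lay 1.17 log2 above its matched lists (percentile 98.54), with S100a8 at 18.0 and 50.9 TPM. Among the 10 genes with the highest differences were Igfbp4, at 23.1 and 701 TPM, Sgk1, at 13.8 and 339 TPM, Slc16a3, a lactate transporter, at 14.3 and 369 TPM, and the mast cell tryptases Tpsb2 and Tpsab1, listed at 0 in MigRI and at 34.7 and 21.8 TPM with Klf4. Among the 10 lowest were Ltb, the cytokine lymphotoxin beta, at 787 and 30.9 TPM, Nrgn, at 355 and 9.17 TPM, Dapl1, at 591 and 21.3 TPM, and Ccdc38, at 129 and 1.04 TPM.

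Lists inside the middle 95% of random lists were effector cytokines and chemokines, exhaustion transcription factors, progenitor and memory genes and effector-like genes, with medians relative to matched lists of -0.41, -0.72, -0.77 and -0.65. Ifng was at 931 and 1970 TPM, and Tnf at 13.6 and 138 TPM, relative log2 differences of 0.29 and 2.46. Tox, a transcription factor of exhaustion, was at 7.89 and 0.612 TPM, a relative log2 difference of -3.26. All list medians in this paragraph are relative to matched lists. Proliferation genes, cyclin-dependent kinase inhibitors, oxidative phosphorylation genes, chemokine receptors and interleukin feedback genes had medians of 0.23, -0.58, 0.64, -0.46 and -0.36. The CD4 T cell, B cell, dendritic cell, erythroid and sex-linked lists had medians of -0.90, -1.21, 0.22, -0.82 and -1.22. Of the tumour keratin list, 2 genes were measured, Lgals4 at 1.28 and 1.35 TPM and Pmel at 0.655 and 0.775 TPM.

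Over all measured genes, 5491 were at least 2-fold higher and 1289 at least 2-fold lower with Klf4 as deposited, and 2691 and 2972 relative to the median gene. The share of these calls that were higher was 81.0% as deposited and 47.5% relative to the median gene. Of 30 lists with a percentile, 11 lay above and 5 below, where 1.5 would fall outside if list members varied independently. Genes of the same list can vary together and some lists share genes, so more than 1.5 can fall outside without any effect of Klf4. Against the receptor constant genes the medians of the 11 lists above were from 2.74 to 4.61 log2. The calls ended for Kruppel-like factors at a filter of 10 TPM, for mitochondrially encoded transcripts without a filter and under quantile normalization, for neutrophil and mast cell genes under median of ratios scaling, and for housekeeping genes without a filter or with length matching. Progenitor and memory genes, which were inside, went below at filters of 5 and 10 TPM, under quantile normalization, without mitochondrial, ribosomal protein and receptor segment genes, and with length matching (lowest percentile 0.27). So did exhaustion transcription factors at a filter of 5 TPM and with length matching, effector-like genes at filters of 5 and 10 TPM, and effector cytokines and chemokines without a filter. Proliferation genes at a filter of 10 TPM, and oxidative phosphorylation genes at that filter and under quantile normalization, went above.

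**Figure D2:**
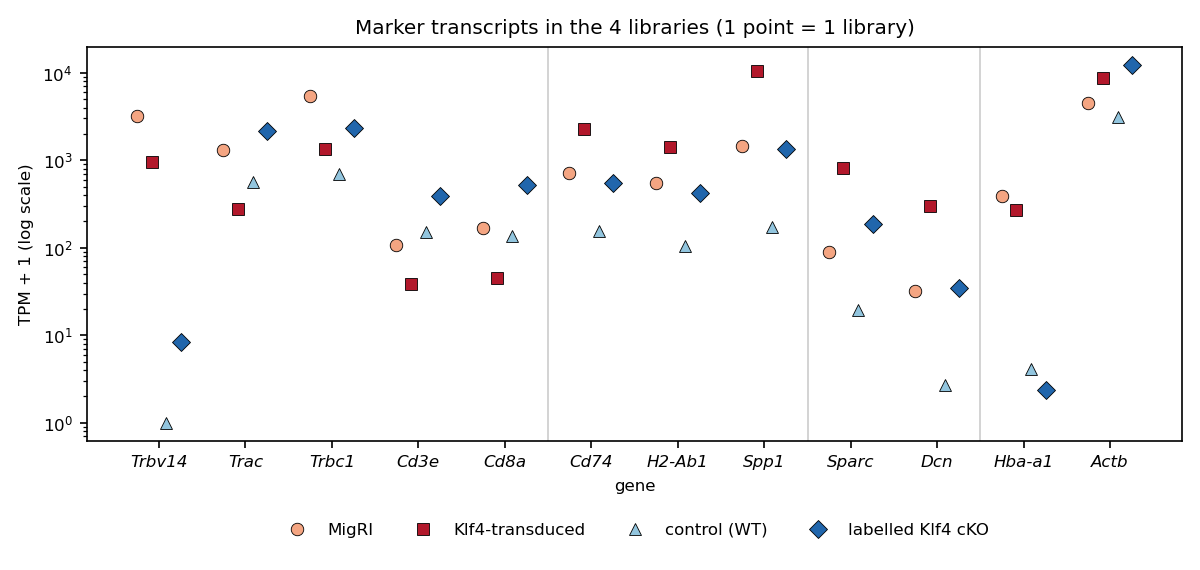
Level of T cell receptor and coreceptor genes (Trbv14 to Cd8a), antigen presentation and macrophage genes (Cd74 to Spp1), fibroblast genes (Sparc and Dcn), and Hba-a1 and Actb in each of the 4 libraries (y axis, TPM + 1, log scale). Each point is 1 library. Trac was at 1295 TPM in MigRI and 274 TPM with Klf4, and at 556 TPM in control and 2164 TPM in the library labelled Klf4 cKO.

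The comparison of the library labelled Klf4 cKO with control asked which transcripts differed in PD1-positive CD8 T cells of mice labelled as lacking Klf4. Cytolytic genes, inhibitory receptors and glycolytic enzymes were higher in the library labelled Klf4 cKO. Gzmb was at 402 TPM in control and 3154 TPM in that library, and Gzmk at 26.5 and 206 TPM, relative log2 differences of 2.23 and 2.18. Ctla4 was at 51.5 and 274 TPM and Tigit at 9.41 and 71.6 TPM, relative log2 differences of 1.65 and 2.06. Macrophage and housekeeping genes were higher in the same library: Cd74 was at 154 and 548 TPM, and Actb at 3140 and 12279 TPM. The Klf4 level does not check the label of this library.

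Of 18 measured cytolytic genes, 9 were at least 2-fold higher and 0 lower relative to the median gene, and the list lay 0.73 log2 above its matched lists (percentile 99.78). As deposited, 15 were higher and 0 lower. Gzmc was at 199 and 877 TPM and Ctsw, a granule protease, at 163 and 797 TPM, relative log2 differences of 1.40 and 1.54. Prf1 was at 58.9 and 166 TPM, a relative log2 difference of 0.74, and Nkg7 at 17171 and 17548 TPM, a relative log2 difference of -0.71. Trac, Trbc1 and Trbc2 were 3.38-fold higher in median, and against them the cytolytic median differed by -0.06 log2.

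Inhibitory receptors lay 0.73 log2 above their matched lists (percentile 99.78), with 5 of 13 at least 2-fold higher relative to the median gene and 0 lower, and 10 higher as deposited. Pdcd1 was at 91.2 TPM in control and 409 TPM in the library labelled Klf4 cKO, and Cd244a at 1.77 and 19.9 TPM, relative log2 differences of 1.42 and 2.18. Havcr2, which encodes TIM3 and was chosen after its values were seen, was at 22.1 and 47.6 TPM, a relative log2 difference of 0.34, and the sign of its deposited difference turned under median of ratios scaling. Against the receptor constant genes the inhibitory receptor median was -0.18 log2. Glycolytic genes lay 1.05 log2 above theirs (percentile 100), with 9 of 15 higher and 1 lower. Against the receptor constant genes the glycolytic median was 0.17 log2. Ldha was at 281 and 1781 TPM, Tpi1 at 116 and 758 TPM and Gapdh at 245 and 1270 TPM.

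Macrophage and monocyte genes lay 0.85 log2 above their matched lists (percentile 99.83), with 9 of 15 at least 2-fold higher relative to the median gene and 0 lower. Fibroblast and endothelium genes lay 0.80 log2 above theirs (percentile 99.395), with 3 of 9 higher and 0 lower. Dcn was at 1.71 TPM in control and 34.0 TPM in the library labelled Klf4 cKO, and Sparc at 18.4 and 186 TPM. Housekeeping genes lay 0.85 log2 above theirs (percentile 99.6), with 8 of 12 higher relative to the median gene and 12 of 12 as deposited. Against the receptor constant genes the macrophage, fibroblast and housekeeping medians were 0.10, -0.28 and 0.06 log2. The erythroid list lay 1.62 log2 below its matched lists (percentile 0.8), with Hba-a1 at 3.17 and 1.37 TPM.

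Among the 10 highest differences were Snx22, at 0.268 TPM in control and 97.9 TPM in the library labelled Klf4 cKO, Fabp4, a lipid carrier, at 1.94 and 68.8 TPM, Il1b, an inflammatory cytokine, at 16.1 and 194 TPM, and Cxcl10, an interferon-induced chemokine, at 19.5 and 210.1 TPM. The mast cell proteases Mcpt2, Cma1 and Tpsb2 were listed at 0 in control and at 29.3, 20.9 and 21.1 TPM in the library labelled Klf4 cKO. Among the 10 lowest were Map3k12, at 45.7 and 0.342 TPM, Fam166a, at 32.8 and 0.577 TPM, Cnot3, at 291 and 18.8 TPM, and Arpp19, at 1080 and 136 TPM.

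Lists inside the middle 95% were effector cytokines and chemokines, exhaustion transcription factors, progenitor and memory genes and effector-like genes, with medians relative to matched lists of 0.42, 0.22, -0.02 and 0.71. Ifng was at 203 and 901 TPM, a relative log2 difference of 1.41, and Tox at 5.35 and 13.3 TPM, a relative log2 difference of 0.44. All list medians in this paragraph are relative to matched lists. The AP-1, early response, Kruppel-like factor, proliferation and cyclin-dependent kinase inhibitor lists had medians of -0.01, 0.52, 0.02, 0.16 and -0.06. Interferon-stimulated, oxidative phosphorylation, mitochondrially encoded, and heat shock and dissociation stress genes had medians of 0.27, 0.59, 0.18 and 0.29. Receptor complex, costimulatory, chemokine receptor and interleukin feedback genes had medians of 0.23, 0.49, 0.33 and 0.13. The CD4 T cell, gamma delta T and NK cell, B cell, dendritic cell, neutrophil and mast cell, and sex-linked lists had medians of -0.64, 0.74, 0.10, 0.13, -0.60 and 0.44. Lgals4 and Pmel were at 2.72 and 4.00 TPM in control and 5.93 and 1.84 TPM in the library labelled Klf4 cKO.

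Over all measured genes, 4826 were at least 2-fold higher and 870 at least 2-fold lower in the library labelled Klf4 cKO as deposited, and 1560 and 2034 relative to the median gene. The share of calls that were higher was 84.7% as deposited and 43.4% relative to the median gene. Of 30 lists with a percentile, 6 lay above and 1 below, where 1.5 would fall outside if list members varied independently, which genes of the same list may not. The calls ended for fibroblast and endothelium genes at a pseudocount of 0.1 or 5, without a filter, and under median of ratios scaling or quantile normalization, and for erythroid genes with length matching. Gamma delta T and NK cell markers, inside at percentile 97.35, went above under 5 of the 7 alternatives set beforehand that gave a value (pseudocount 0.1, a filter of 5 TPM, median of ratios scaling, quantile normalization, and without the 50 most abundant genes), up to percentile 99.98. Other lists that went from inside to above were effector-like genes, costimulatory receptors and chemokine receptors at a pseudocount of 5, early response genes without a filter or without mitochondrial, ribosomal protein and receptor segment genes, and oxidative phosphorylation genes at filters of 5 and 10 TPM.

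**Figure D3:**
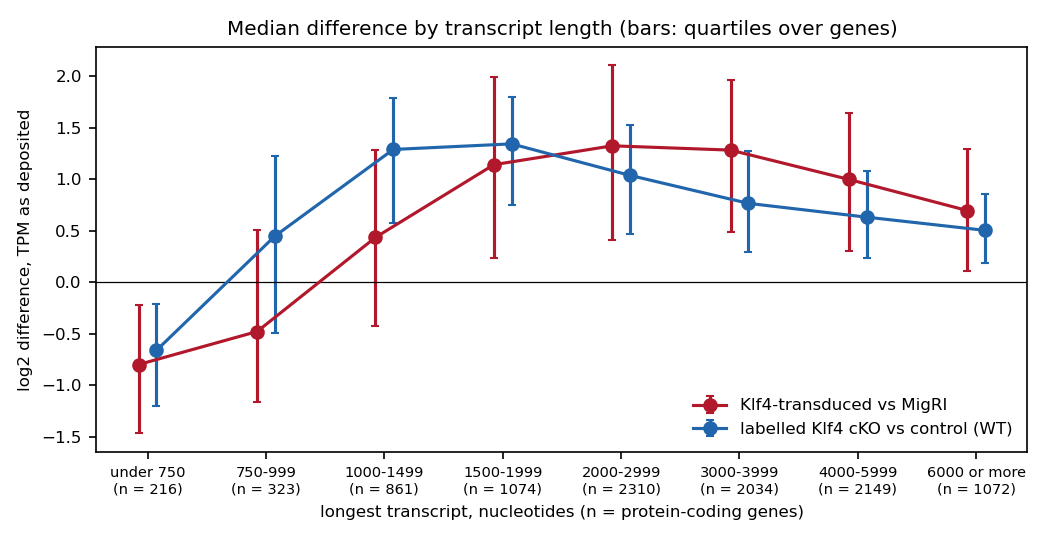
Median log2 difference of protein-coding genes (y axis, TPM as deposited) by longest transcript in nucleotides (x axis), for Klf4-transduced over MigRI and for the library labelled Klf4 cKO over control, with bars for the quartiles over genes. Genes under 750 nucleotides had medians of -0.80 and -0.66, and genes of 1500 to under 2000 nucleotides had medians of 1.14 and 1.34.

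The last comparison set gain against loss and asked whether genes differed in opposite directions in the 2 experiments. Genes were ranked by the smaller of the 2 differences, leaving out receptor segments and the other classes that the naming rule drops. The first opposite gene was Tmem200b, higher with Klf4 and lower in the library labelled Klf4 cKO, with deposited log2 differences of 3.15 and -3.05. S100a9 had 1.52 and -2.78, Homer3 1.91 and -1.66 and Mindy1 2.74 and -1.56. In the other direction, Tigit had -2.72 and 2.80, Ctla4 -2.26 and 2.39, Gzmc -2.92 and 2.13, and Ctsw -2.54 and 2.28. Cd8b1, a CD8 coreceptor chain, had -2.12 and 2.33, and Klrc1, an inhibitory NK receptor, had -2.37 and 2.19. The other genes named in that direction were Rnf113a2, with -2.42 and 2.48, Tesc, with -3.21 and 2.30, Rarres2, with -2.20 and 2.20, and Phf11c. Phf11c was at 20.5 TPM in MigRI and listed at 0 with Klf4. It was at 4.39 TPM in control and 23.4 TPM in the library labelled Klf4 cKO. The receptor constant genes Trac, Trbc1 and Trbc2, which the ranking left out, had median differences of -2.02 and 1.76. Relative to them, Tigit had -0.706 and 1.044, Ctla4 -0.245 and 0.629, Gzmc -0.909 and 0.376, and Ctsw -0.528 and 0.524. Cd8b1 had -0.099 and 0.570, Klrc1 -0.352 and 0.437, and Rnf113a2 -0.409 and 0.723. Tesc had -1.195 and 0.546, and Rarres2 -0.188 and 0.447.

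As deposited, 282 genes were lower with Klf4 and higher in the library labelled Klf4 cKO, where independent lists of these sizes would share 495, and 66 genes were the reverse, where independent lists would share 380. Genes higher in both numbered 2553 against 2108, and genes lower in both 359 against 89.2. Relative to the median gene, the opposite classes held 230 and 89 genes against 369 and 435, and the classes of higher and lower in both held 404 and 1190 against 334 and 481. Across the 12570 genes, which are not independent replicates, the differences of the 2 experiments had a Pearson r of 0.33 and a Spearman rho of 0.30. With the receptor constant genes as reference, which shifts all genes of a comparison alike and leaves r as it is, 5491 genes were higher with Klf4 and lower in the library labelled Klf4 cKO against 5768 for independent lists, 3 were the reverse against 0.868, 95 were higher in both against 97.2, and 65 lower in both against 51.5. The comparisons share no library, and the directions from the library labelled Klf4 cKO rest on its label.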

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

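The test for RNA of other cells, the test for a larger T cell share and the test against lists matched on level were chosen after the results were seen. A further signal within the loss comparison lay in the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Their summed level was 32.9 TPM in the library labelled Klf4 cKO against 2.92 TPM in control, and 0 in both Pmel-I libraries. The 2 libraries of the loss experiment thus differed in Y-linked RNA. The cause was not tested and cannot be told apart from the label in any difference between these libraries. Eif2s3y was at 27.2 TPM and 2.47 TPM in the library labelled Klf4 cKO and in control.

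T cell receptor genes were lower, and macrophage and fibroblast genes higher, in the Klf4-transduced library. Relative to lists matched on level and longest annotated transcript, the receptor complex list stayed at -2.28 log2 (percentile 0). This argues against a trend with annotated length as the whole cause. The matching used 5 length classes, so a trend within a class stays open. The expressed transcripts may be shorter, so bias by their length stays open. RNA of macrophages and fibroblasts stays open: the lower of the 2 list medians was 1.79 log2 above matched lists, but this value is part of the pattern itself and does not support the explanation. Cd74 reached 2251 TPM, H2-Ab1 1424 TPM and Sparc 821 TPM, although the isolation was of GFP-positive CD8 T cells. MigRI, isolated in the same way, already held Cd74 at 711 TPM and H2-Ab1 at 549 TPM. The purity of the isolated cells could not be checked. A change of these genes within T cells through Klf4 also stays open and was not tested, since the design has 1 library per group.

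Cytolytic genes were higher in the library labelled Klf4 cKO. The list stayed at 0.66 log2 with length matching (percentile 99.53), which argues against annotated length as the whole cause. The matching used 5 length classes, so a trend within a class stays open, as does bias by the length of the expressed transcripts. A rise of abundant transcripts in general stays open. The list lay 0.73 log2 above lists matched on level (percentile 99.78), but this value is the one that called the list. Housekeeping genes also lay above theirs, by 0.85 log2. A larger share of T cell RNA stays open: Trac, Trbc1 and Trbc2 were 3.38-fold higher and the cytolytic median minus theirs was -0.06 log2, while the macrophage list, which a larger T cell share alone would lower, lay 0.85 log2 above its matched lists and 0.10 log2 above the receptor genes. An effect of Klf4 loss stays open and untested, and the Klf4 level does not check the label.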

How the results depend on the processing

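Alternatives named as references to the median gene or to the receptor constant genes (Trac, Trbc1 and Trbc2), as matched on length or as only coding genes were chosen after seeing the data. With 1 library per group, no library could be left out. No paired analysis was possible because each group holds 1 library and the comparisons use no test. Keeping the highest of several entries for 1 symbol gave no separate value, since no usable symbol was repeated. Depth, unknown for TPM, limits what low genes can show. Of 23 lists outside the percentiles, 18 stayed on the same side under every alternative set beforehand that gave a value and 5 went inside under at least 1, and 12 of 37 lists inside went outside under at least 1. Of these 60 lists, 14 were left with fewer than 3 genes under at least 1 of the 9 alternatives, which then gave no value, and the fewest that gave one were 7. Among named genes at least 2-fold as deposited, 3 changed sign under an alternative set beforehand: Aurka, and Havcr2 and Trbv13-2, which were chosen after their values were seen, all under median of ratios scaling. With the receptor constant genes as reference, the sign changed for 16 of 167 such genes for Klf4 over MigRI and 61 of 180 for the library labelled Klf4 cKO over control, counted without the 3 constant genes but with the other genes chosen after their values were seen, and for 944 of 6780 and 3348 of 5696 measured genes. List medians with that reference are plain list medians minus the receptor median, without matched lists. Their change comes from the subtraction and from leaving out the matched lists. Exhaustion transcription factors and progenitor and memory genes went outside for Klf4 over MigRI with length matching, at percentiles 1.775 and 1.125. In what follows, cKO stands for the library labelled Klf4 cKO, and list medians are medians relative to matched lists. The exception is the receptor constant genes as reference, whose list medians cannot be compared with the others. For the other changes the cause was not tested, except that stricter filters leave fewer genes. A pseudocount of 0.1 put list medians of Klf4 over MigRI at cytolytic effector molecules -2.18, interferon-stimulated genes 1.54 and neutrophils and mast cells 2.58. A pseudocount of 0.1 put list medians of cKO over control at erythroid -2.39. With a pseudocount of 0.1, both experiments gave 554 opposite genes. With a pseudocount of 5, Klf4 over MigRI gave 3567 genes higher and 793 genes lower. A pseudocount of 5 put list medians of Klf4 over MigRI at cytolytic effector molecules -1.05, inhibitory receptors -0.82, gamma delta T and NK cells -1.21 and fibroblasts and endothelium 1.25. With a pseudocount of 5, cKO over control gave 2650 genes higher and 496 genes lower. A pseudocount of 5 put list medians of cKO over control at fibroblasts and endothelium 0.32 and erythroid -1.05. With a pseudocount of 5, both experiments gave 156 opposite genes. No filter put list medians of Klf4 over MigRI at mitochondrially encoded transcripts 0.77 and gamma delta T and NK cells -1.21. No filter put list medians of cKO over control at fibroblasts and endothelium 0.27. With a mean of at least 5 TPM, Klf4 over MigRI gave 3388 genes higher. A mean of at least 5 TPM put list medians of Klf4 over MigRI at interferon-stimulated genes 1.61. With a mean of at least 5 TPM, cKO over control gave 551 genes lower. A mean of at least 5 TPM put list medians of cKO over control at fibroblasts and endothelium 1.68. With a mean of at least 10 TPM, Klf4 over MigRI gave 2350 genes higher and 831 genes lower. A mean of at least 10 TPM put list medians of Klf4 over MigRI at inhibitory receptors -2.82, AP-1 family 2.12 and fibroblasts and endothelium 2.63. With a mean of at least 10 TPM, cKO over control gave 432 genes lower. A mean of at least 10 TPM put list medians of cKO over control at fibroblasts and endothelium 1.84. With a mean of at least 10 TPM, both experiments gave 214 opposite genes and a correlation across genes of 0.46. With median of ratios scaling, Klf4 over MigRI gave 2435 genes higher, 2674 genes lower and a Klf4 difference of 0.61. Median of ratios scaling put list medians of Klf4 over MigRI at gamma delta T and NK cells -2.07. With median of ratios scaling, cKO over control gave 994 genes higher, 2751 genes lower and a Klf4 difference of -0.79. Genes of cKO over control whose sign turned with median of ratios scaling were Aurka -0.00023, Havcr2 -0.047 and Trbv13-2 -0.0060. With quantile normalization, Klf4 over MigRI gave 2407 genes higher, 2659 genes lower and a Klf4 difference of 0.40. Quantile normalization put list medians of Klf4 over MigRI at AP-1 family 2.10 and glycolysis 2.56. With quantile normalization, cKO over control gave 1903 genes higher, 2002 genes lower and a Klf4 difference of -0.57. With the median gene as reference, Klf4 over MigRI gave 2691 genes higher, 2972 genes lower and a Klf4 difference of 0.69. With the median gene as reference, cKO over control gave 1560 genes higher, 2034 genes lower and a Klf4 difference of -0.47. With the receptor constant genes as reference, Klf4 over MigRI gave 11312 genes higher, 101 genes lower and a Klf4 difference of 3.50. The receptor constant genes as reference put list medians of Klf4 over MigRI at cytolytic effector molecules 0.62, inhibitory receptors 1.55, AP-1 family 4.02, T cell receptor-induced early response genes 3.61, Kruppel-like factors 3.98, interferon-stimulated genes 3.59, glycolysis 3.91, mitochondrially encoded transcripts 2.74, heat shock and dissociation stress 3.54, T cell receptor complex 0.32, costimulatory and interleukin 2 receptors 0.74, gamma delta T and NK cells 0.17, macrophages and monocytes 4.35, neutrophils and mast cells 4.11, fibroblasts and endothelium 4.61 and housekeeping genes 3.05. Genes of Klf4 over MigRI whose sign turned with the receptor constant genes as reference were Arpp19 0.32, Ccdc167 0.30, Ccr7 0.83, Cd28 0.60, Cd3e 0.54, Cd8a 0.11, Cenpf 0.24, Cox5a 0.15, Cxcr3 0.72, Gzmk 0.75, Icos 0.41, Mcmdc2 0.60, Ndufb8 0.087, Pdcd1 0.27, Trav7d-5 0.12, Trbc2 0.16 and Trbv14 0.25. With the receptor constant genes as reference, cKO over control gave 108 genes higher, 6409 genes lower and a Klf4 difference of -1.49. The receptor constant genes as reference put list medians of cKO over control at cytolytic effector molecules -0.059, inhibitory receptors -0.18, glycolysis 0.17, macrophages and monocytes 0.10, fibroblasts and endothelium -0.28, erythroid -2.34 and housekeeping genes 0.059. Genes of cKO over control whose sign turned with the receptor constant genes as reference were ATP8 -0.36, Atp5a1 -0.13, Aurka -0.74, Batf -0.48, Bhlhe40 -0.24, COX3 -0.21, CYTB -0.24, Cacnb3 -0.55, Capn6 -0.025, Cd226 -0.35, Cd3e -0.38, Cd3g -0.48, Cdkn2b -0.39, Cdkn2c -0.068, Cdkn2d -0.35, Dnajb1 -0.10, Egr1 -0.089, Fos -0.013, Fosl1 -0.28, Gpr183 -0.15, Gusb -0.35, Havcr2 -0.68, Hspa1a -0.54, Hspa1b -0.50, Hspa5 -0.20, Hspa8 -0.46, Ifit3 -0.0081, Ighm -0.030, Il18r1 -0.29, Junb -0.22, Klf3 -0.15, Klf6 -0.22, Klf7 -0.36, Klra4 -0.73, Klre1 -0.38, Klrk1 -0.26, Lat -0.36, Mafg -0.11, Mcl1 -0.24, Mcm5 -0.24, Mmp11 -0.29, Myc -0.11, ND1 -0.56, Nr4a2 -0.41, Oasl1 -0.25, Pkm -0.19, Plk1 -0.63, Prf1 -0.28, Rsad2 -0.21, Sdha -0.61, Sgk1 -0.073, Slc16a3 -0.36, Socs1 -0.25, Socs2 -0.24, Socs3 -0.53, Stat3 -0.25, Tnfrsf18 -0.20, Tnfrsf4 -0.35, Tox -0.58, Tpsab1 -0.37, Trbc2 -0.021 and Trbv13-2 -0.62. With the receptor constant genes as reference, both experiments gave 5494 opposite genes. With only coding genes of at least 1000 nucleotides, Klf4 over MigRI gave 571 genes lower. With only coding genes of at least 1000 nucleotides, cKO over control gave 282 genes lower. With only coding genes of at least 1000 nucleotides, both experiments gave 217 opposite genes. Lists matched on level and length put list medians of Klf4 over MigRI at glycolysis 1.39.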

Other observations

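The receptor genes, Spp1, Tcf7 and Mki67 were chosen after their values were seen. Trbv segments differed between the experiments, and Trav segments less clearly. Trbv14 was at 3229 TPM in MigRI and 947 TPM with Klf4, took 99.1% and 98.6% of all Trbv TPM, and was listed at 0 in control and at 7.43 TPM in the library labelled Klf4 cKO. In control and in the library labelled Klf4 cKO, 17 and 20 Trbv segments reached 1 TPM, and the highest, Trbv12-2 and Trbv16, took 23.1% and 24.8%. Trav segments at 1 TPM or more numbered 44 in MigRI, 7 with Klf4, 55 in control and 84 in the library labelled Klf4 cKO. All Trav segments together had 447, 100, 326 and 646 TPM in the same order. A count above a fixed level depends on this total, so it does not compare the range of receptors. The highest in the Pmel-I libraries, Trav7d-5, took 29.2% and 34.3% of all Trav TPM. Trbv13-2 was listed at 0 in both Pmel-I libraries and was at 58.5 and 130 TPM in control and in the library labelled Klf4 cKO.

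The mast cell proteases Tpsb2 and Mcpt2 were listed at 0 in MigRI and control and were seen in both of the other libraries. Tpsb2 was at 34.7 TPM with Klf4 and 21.1 TPM in the library labelled Klf4 cKO, and Mcpt2 at 16.6 and 29.3 TPM. Hemoglobin genes marked the gain experiment, with Hba-a1 at 388 and 270.0 TPM there and at 3.17 and 1.37 TPM in the loss experiment. Spp1, a secreted protein of macrophages and of tumour cells, was at 1472 TPM in MigRI, 10552 TPM with Klf4, 173 TPM in control and 1352 TPM in the library labelled Klf4 cKO. Tcf7, a factor of progenitor cells, was at 2.80, 4.04, 0.988 and 0.989 TPM in the same order, and Mki67, a proliferation marker, at 4.76, 3.01, 3.84 and 5.13 TPM.

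As deposited and relative to the median gene, genes differed in the same direction in both experiments more often than in opposite directions. Counts relative to Trac, Trbc1 and Trbc2 do not bear on this, since that reference shifts each gene up in the gain comparison and down in the loss comparison. One hypothesis was a trend with level and transcript length shared by both comparisons. After the median of each level and length class was subtracted, the correlation across 11761 genes was 0.313, against 0.304 before. A trend between classes of level and longest annotated transcript is thus argued against as the whole cause. A trend within a class was not removed by the subtraction and stays open, as does one with expressed length. What else the 2 libraries have in common, such as RNA of other cells, stays open.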
